A study of Mus musculus with 12 samples.

How the data were processed

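The arrays measured RNA from mouse eye primordia at embryonic day 10.5. Embryos were frozen and cut into 10 µm sections, and the distal optic vesicle (the prospective retina) and the surface ectoderm over it (the prospective lens) were taken by laser microdissection from wild-type (WT) embryos and from embryos with Bmp4 deleted in the optic vesicle (KO). Per the labels, the starting amount was 15 ng of RNA, copied into cDNA with a pico-scale amplification kit, biotin labelled and hybridised to Illumina bead arrays. The series has 12 arrays in 4 groups of 3: WT and KO optic vesicle, and WT and KO surface ectoderm. The design text speaks of 3 embryos per genotype and of pooled RNA. The labels do not settle whether the 3 arrays of a group are separate embryos or repeats of a pool, so the p-values may measure only technical spread.

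The deposited scanner-level table holds, per probe and array, the mean bead intensity on a linear scale, its bead standard error as intensity, the number of beads (unit: other) and a detection p-value (p_value), the share of negative control probes at least as bright. Per the file headers these come from GenomeStudio, whose version is not stated, and the intensity is neither background-subtracted nor normalised between arrays. The authors also deposited a matrix of processed intensity values for the same arrays. It is on a linear scale, its values start below 0, and its column medians are nearly equal: 9.40, 9.42 and 9.41 for KO optic vesicle replicates 1 to 3, 9.41, 9.41 and 9.40 for KO surface ectoderm, 9.41, 9.41 and 9.41 for WT optic vesicle, and 9.40, 9.41 and 9.41 for WT surface ectoderm. Each column ranked its probes like the scanner values of its own array (Spearman rho 1) and less like any other array (rho at most 0.867), so its direction is that of the scanner values. The background and normalisation options behind it are not stated, and its centring is known only from the values. It served as an alternative.

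Scanner intensities were normalised with neqc of limma 3.58.1 in R 4.3.3: background correction with controls inferred from the detection p, an offset of 16, quantile normalisation and log2. A probe was kept if its detection p was below 0.05 on at least 3 of the 12 arrays, which left 24978 of 45281 probes. In the platform annotation 34885 probes have 1 gene symbol, 18 have several and 10378 have none. Of the named probes 34807 had an Entrez ID in the RefSeq table of the mouse genome build GRCm38, which changed 0 symbols. Probes with several symbols or none were not named. Each of the 11924 genes tested was represented by its kept probe with the highest mean over all arrays; 5261 genes had over 1 kept probe. A gene is called detected on an array where the detection p of its used probe is below 0.05.

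Group differences were tested with limma (lmFit, eBayes with trend) on all 12 arrays, with Benjamini-Hochberg adjusted p below 0.05, two-sided; every adjusted p of a gene is from this model. KO was set against WT in each tissue without a block. The tissue comparisons within each genotype and the difference of the genotype effects between the tissues (the interaction) used the embryo number within genotype as a fixed block. Residuals of samples that share a number correlated between -0.04 and 0.03, so the numbers gave no sign of pairing. Of 24 gene lists fixed before the data were examined, 23 had at least 4 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation. The lists cover BMP targets and BMP pathway components, neural retina, pigment epithelium, dorsal and ventral retina, other forebrain, lens placode, surface ectoderm, mesenchyme, endothelial, erythroid and macrophage markers, cell cycle, CDK inhibitors and p53 targets, FGF/ERK, Wnt, Hedgehog, Notch and retinoic acid pathways, neurogenesis, extracellular matrix, hypoxia and glycolysis, and immediate early genes. Members of a list were also counted with p adjusted over the list alone. Some genes sit on several lists, Fgf15, Tbx3 and Sox2 among them, so the list results are not independent of each other. The entry Cdo of the ventral retina list is an older name of both Cdo1 and Cdon. It was left out after the results had been seen, and the alternatives give both readings.

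Genes are named by a rule set before the data were examined. It takes Bmp4, the BMP targets that passed, the 10 largest changes in each direction with all KO values on one side of all WT values, and up to 4 members of each list with the lowest p. For the interaction it takes the 5 genes with the lowest adjusted p, and for the tissue comparisons the 5 largest changes in each direction and up to 3 members of each of 5 tissue lists. Other genes are named only where they complete a small count or are singled out, and the text then says that they lie outside the rule; these were chosen after their values were seen.

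The pipeline was tested on simulated data with 1 spread per gene, estimated from the arrays over all 4 groups. Of 100 genes shifted by 1 and 100 shifted by 2 on the log2 scale, 24% and 81% were recovered in the optic vesicle comparison and 31% and 77% in surface ectoderm. The shares were 9% and 26% for the interaction, 17% and 61% for the tissues in WT, and 10% and 64% for the tissues in KO. False calls made up 0% to 4.88% of the calls. A list shifted by 1 was called in both genotype comparisons, with 0 of 21 unrelated lists. The simulated genes varied independently of each other, and both tissues had the same spread. In the arrays the median SD of a gene was 0.28 in KO and 0.26 in WT optic vesicle, and 0.36 and 0.32 in surface ectoderm. The simulation therefore cannot show how often genes or lists are called falsely where genes vary together, as in real arrays. It also cannot show recovery or false calls where the tissues differ in spread.

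Alternatives were no background correction, median scaling, the authors' processed values, no filter and a stricter filter on detection, the mean of a gene's probes, slide as a block, array weights, other thresholds, other blocks, only the arrays of 1 tissue, other set tests, and leaving out each array. The arrays sit on 2 slides of 6, and each slide holds arrays of all 4 groups. The number of arrays limits the precision.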

Results

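Expression arrays compared eye primordia of WT embryos and of embryos with a deletion of Bmp4, which encodes a secreted growth factor of the prospective retina, in the optic vesicle. Each of the 4 groups had 3 arrays: distal optic vesicle and surface ectoderm, each from WT and from KO embryos. Between 45.0% and 46.7% of the 45281 probes were detected per array, the median raw intensity per array ran from 85.7 to 123, and a probe value rested on a median of 42 beads. Replicates of a group correlated across genes at 0.961 to 0.963 in WT optic vesicle, 0.950 to 0.957 in KO optic vesicle, 0.933 to 0.945 in WT surface ectoderm and 0.929 to 0.930 in KO surface ectoderm. The first principal component held 29.3% of the variance, the second 16.3% and the third 8.83%. Values below are normalised log2 intensities as mean ± SD (n = 3 arrays per group).

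The first question was whether the deleted gene was lower. Bmp4 (Entrez 12159, chromosome 14 of GRCm38, 46383525 to 46390669) fell from 8.26 ± 0.04 in WT optic vesicle to 4.59 ± 0.51 in KO optic vesicle (n = 3 each), a log2 change of -3.67, with limma adjusted p = 0.00010. The probe was detected on 3 of 3 WT and 1 of 3 KO arrays, so the fall was at least 10.4-fold. Such a bound sets the brighter group's mean against, per dim array, the higher of the lowest detected signal and the probe's own value. In surface ectoderm Bmp4 stood at 6.02 ± 0.11 in WT, dimmer than in WT optic vesicle, and at 4.92 ± 0.64 in KO, and this log2 difference between the genotypes of -1.10 did not pass (limma adjusted p = 0.14). A second, dimmer probe gave 6.34 ± 0.07 in WT and 5.22 ± 0.37 in KO optic vesicle (detected on 3 of 3 KO arrays), which did not pass (limma adjusted p = 0.48). On that probe KO surface ectoderm replicates 1 to 3 stood at 7.11, 4.78 and 4.58, and WT surface ectoderm at 4.31, 4.23 and 4.24, not above background. Replicate 1 of KO surface ectoderm lay above every WT array. In surface ectoderm this direction is opposite to that of the used probe, so the direction of Bmp4 there is not settled. Whether either probe lies in the deleted part of the gene is not known from the labels, and a probe outside it would not measure the deletion. Without background correction the optic vesicle change of Bmp4 was -1.99. Within slide 1 the Bmp4 change was -3.08 in optic vesicle and -0.90 in surface ectoderm, within slide 2 it was -3.97 and -1.52, and a slide block, which cannot move these differences because each tissue has as many KO as WT arrays on a slide, gave adjusted p = 0.00016 and adjusted p = 0.13.

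**Figure D1:**
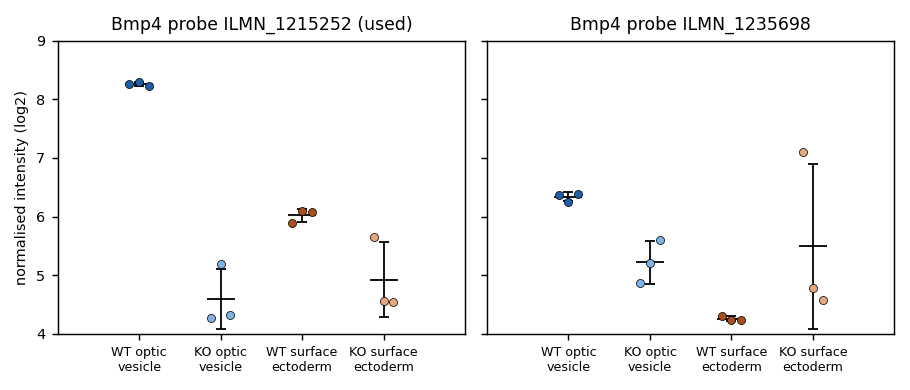
Normalised log2 intensity of Bmp4 on each of the 12 arrays for both of its probes, with the mean and SD of each group of 3. The used probe stood near 8.26 in WT optic vesicle and near 4.59 in KO optic vesicle.

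The second question was how expression in the prospective retina changed in KO embryos. In KO optic vesicle the dorsal retinal genes Aldh1a1, a retinoic acid synthesising enzyme, and Tbx3, a T-box transcription factor, fell 23.4-fold and at least 16.7-fold, and the growth factor gene Fgf15 fell 9.65-fold. The transcription factor Sox2 fell 4.93-fold, from 10.49 ± 0.13 to 8.19 ± 0.23 (n = 3 each). In the same arrays the melanosome gene Pmel rose 18.3-fold, from 6.24 ± 0.28 to 10.44 ± 0.04 (n = 3 each), and Otx2, a transcription factor of the pigment epithelium, rose 3.14-fold. Embryonic globins and Postn, a gene of the mesenchyme list, also rose in these samples, Hbb-y 2.41-fold and Postn by 3.46 on the log2 scale.

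Genes that answer to BMP signalling were lower as a group in KO optic vesicle. Of 12 measured BMP target and feedback genes 2 fell, 0 rose and 10 did not pass, while 6 fell when adjusted over the list alone (median log2 change -0.77, camera adjusted p = 5.1e-07). Tbx3 went from 8.93 ± 0.13 to 4.75 ± 0.35 (detected on 2 of 3 KO arrays) and Id2, a dominant-negative helix-loop-helix factor, from 10.88 ± 0.09 to 9.42 ± 0.22. Id1 at -1.56 and Grem1, a BMP antagonist, at -1.23 did not pass over all genes. Among 17 BMP ligands, receptors and transducers Gdf6 fell with Bmp4 and Bmp7 rose by 2.56, with 14 not passing (adjusted p = 0.21). Gdf6 was not detected on any KO array and was at least 12.4-fold lower.

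Genes of the dorsal retina fell together. Of 7 measured members 3 fell and 4 did not pass, 5 when adjusted over the list alone (median -1.22, adjusted p = 8.0e-11). Aldh1a1 went from 11.27 ± 0.05 to 6.72 ± 0.42 and Efnb2, an ephrin, fell by 2.18. Aldh1a1 has a near-identical neighbour, Aldh1a7, so the probe may read both. Of 7 ventral retina and optic stalk genes only Aldh1a3 rose, by 0.85, and the list was not called (median 0.40, adjusted p = 0.056). Vax1 stood at +1.27 and Bmpr1b at -1.25 without passing.

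Among 18 neural retina and eye field genes 4 fell, 1 rose and 13 did not pass; 7 fell and 2 rose when adjusted over the list alone (median -0.52, adjusted p = 0.00023). Fgf15 went from 9.68 ± 0.06 to 6.41 ± 0.34, Sox2, the cyclin Ccnd1 and, outside the naming rule, Sfrp2 fell, with log2 changes of -2.30, -0.86 and -0.92. The homeobox gene Meis2 rose by 0.62. The probes of Fzd5, a Wnt receptor outside the naming rule here, disagreed in a fit of all probes: the used one stood at -1.42 (adjusted p = 0.26) and a dimmer one at -2.27 (adjusted p = 0.00064). FGF and ERK response genes fell as well, 7 of 12 with 5 not passing and 8 adjusted over the list alone (median -1.32, adjusted p = 1.5e-10). Among them the ETS factor Etv5 went from 7.64 ± 0.26 to 4.88 ± 0.94 (detected on 1 of 3 KO arrays), and the feedback inhibitors Spry2 and Dusp4 fell, with log2 changes of -2.24 and -2.09.

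Pigment epithelium genes had the largest median shift of the 23 lists tested in optic vesicle, with 10 of 16 higher, 0 lower and 6 not passing, and 11 higher when adjusted over the list alone (median 1.73, adjusted p = 5.3e-21). Besides Pmel and Otx2, the melanin enzyme gene Tyrp1 rose from 4.53 ± 0.43 (detected on 1 of 3 WT arrays) to 7.43 ± 0.16, and the gap junction gene Gja1 rose by 0.55. For Mitf, a pigment cell regulator outside the naming rule, the probes disagreed. The used one read 8.68 ± 0.12 in WT and 8.72 ± 0.20 in KO (adjusted p = 0.99), and a dimmer one rose from 5.48 ± 0.26 to 8.11 ± 0.06 (adjusted p = 0.0032). Wnt targets rose as a group, 2 of 12 with 10 not passing, and adjusted over the list alone 3 rose and 1 fell (median 0.54, adjusted p = 0.0088). Sp5, a Wnt-induced transcription factor, rose by 2.10 and Sfrp1, a secreted Wnt inhibitor, by 0.94. Of 12 other forebrain genes the ligands Wnt7b and Wnt5a rose, by 1.69 and 2.10, and 10 did not pass (adjusted p = 0.15).

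Markers of tissues beside the vesicle moved in the same samples. Of 8 erythroid genes 4 rose, 5 adjusted over the list alone (median 1.22, adjusted p = 7.7e-11). Hbb-y rose by 1.27, Hbb-bh1 by 1.16, Hba-x by 1.77 and Hba-a1 by 1.45, and since globin genes resemble each other these are not certain to be separate signals. Of 12 mesenchyme and neural crest genes 2 rose, Postn and the homeobox gene Alx4, and 10 did not pass (median 0.44, adjusted p = 0.0017). Col3a1 and Twist1 were among the 10, at 4.93 to 5.43 and 4.52 to 4.99 in KO vesicle. Postn was not detected on any KO ectoderm array, where Col3a1, Twist1 and Alx4 rose, so its rise alone does not mark mesenchyme. Of 20 surface ectoderm genes the keratin Krt18 rose by 2.04 and 19 did not pass, 3 rising adjusted over the list alone (median 0.30, adjusted p = 0.00053). None of 9 endothelial genes passed (0 higher, 0 lower, median 0.40, adjusted p = 0.20), nor did any of 7 macrophage genes (0 passing, median 0.02, mean -0.02, adjusted p = 0.71).

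The remaining lists were not called in optic vesicle. Of 20 lens placode genes 1 rose and 2 fell, Sox2 and Mab21l1 (adjusted p = 0.71). Of 9 retinoic acid genes Aldh1a3 and the vitamin A receptor Stra6 rose and Aldh1a1 fell (adjusted p = 0.47). Of 17 extracellular matrix genes Lamb1 rose by 1.30 and Vcan fell by 1.03 (adjusted p = 0.26). Of 13 hypoxia and glycolysis genes Tpi1 rose by 0.40 (adjusted p = 0.068), and of 23 cell cycle genes only Ccnd1 fell (adjusted p = 0.52). For CDK inhibitors and p53 targets (12 genes, adjusted p = 0.47), Notch (6, 0.056), neurogenic (7, 0.15) and immediate early genes (8, 0.94) the number passing was 0. Median and mean differed in sign for the lens (0.07 and -0.0019), hypoxia (0.11 and -0.01), immediate early (0.08 and -0.05) and macrophage lists. The Hedgehog list had 3 measured members, Gli1, Hhip and Ptch1, at -0.23, -0.30 and 0.43, and was not tested.

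Among the largest single changes in optic vesicle, Sowaha was at least 41.1-fold lower (0 of 3 KO arrays detected), and Cyp1b1, a cytochrome P450 enzyme, Dapl1 and the synaptic vesicle gene Syt1 fell, with log2 changes of -3.76, -3.39 and -2.79. Rpp25 rose by 4.46, Lrtm1 by 3.90, Smoc1, a BMP-modulating matrix protein, 9.22-fold and Pacsin1 at least 7.41-fold. Ociad2, the kinase gene Sgk1, the platelet chemokine Pf4 and the calcium pump Atp2a3 rose by 3.12, 3.03, 2.99 and 2.99. The probes of Alx4, Atp2a3, Pacsin1 and Sp5 were detected on 1 of 3 WT arrays, so the size of these changes depends on the background level.

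In all, 215 of 11924 genes passed in optic vesicle, 124 higher and 91 lower in KO, with an unadjusted p below 0.05 in 1450. All 215 had the 3 KO values on one side of the 3 WT values, which 21.2% of all genes showed and chance gives for 10%. Of the 9 lists called, 9 stayed below 0.05 with an estimated correlation. With slide as a block 212 genes and 11 lists passed, the ventral (adjusted p = 0.041) and Notch lists (adjusted p = 0.041) being added. Without the block the ventral list had a camera adjusted p of 0.12 with an estimated correlation. Of the lists called without the block, 9 of 9 medians kept their sign within both slides. Within slide 2 (2 arrays per genotype) 65 genes passed. Within slide 1 (1 per genotype) 0 passed, but there the spread comes from the surface ectoderm arrays alone, so this count says nothing about replication in optic vesicle. Of 47 named genes that passed 28 had over 1 kept probe; in 13 another probe passed in the same direction, and in 15 no other probe did. The count was 412 with array weights and 318 in a fit of these 6 arrays alone, and it dropped to 141, 137, 134, 129 and 115 without KO replicates 1 or 2 or WT replicates 1, 2 or 3.

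**Figure D2:**
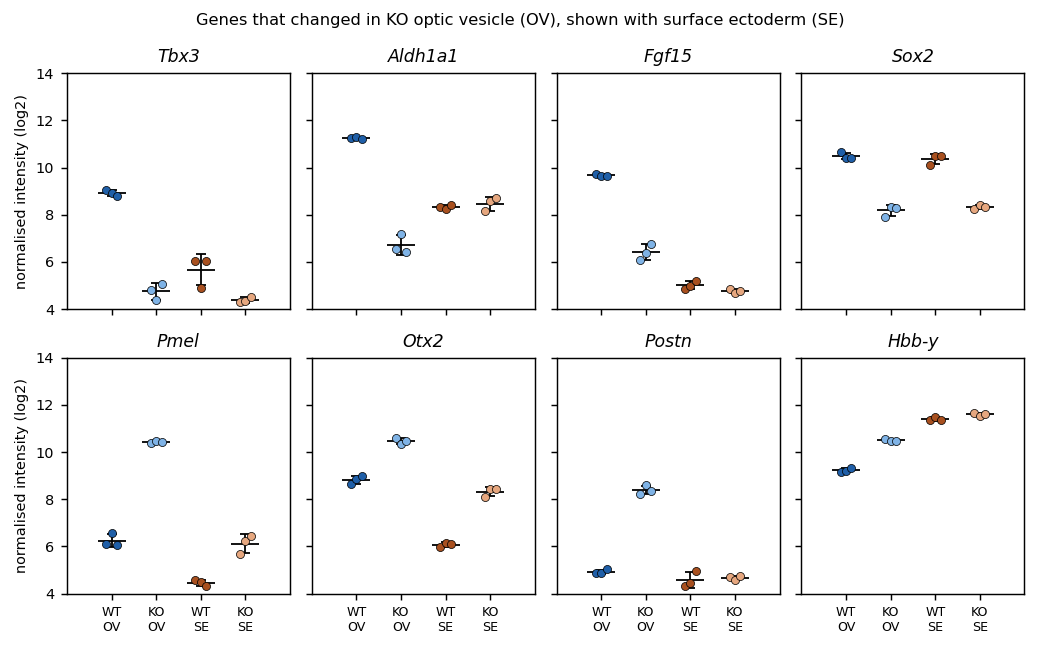
Normalised log2 intensity of 8 genes on each array in all 4 groups, with the mean and SD of each group of 3. In KO optic vesicle Tbx3, Aldh1a1, Fgf15 and Sox2 were lower and Pmel, Otx2, Postn and Hbb-y were higher than in WT.

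The third question was how the prospective lens over the KO vesicle changed. In KO surface ectoderm the lens regulator Prox1 fell 25.8-fold, from 10.07 ± 0.26 to 5.38 ± 0.19 (n = 3 each), and Pitx3, a homeobox gene of the lens, was at least 6.68-fold lower. The ETS factors Etv1 and Etv5 fell 24.0-fold and at least 17.1-fold and Jag1, a Notch ligand, also fell. The epidermal genes Trp63 and Perp rose by 2.58 and 3.27 on the log2 scale, and Wnt6, whose used probe was not detected on any WT array, at least 12.5-fold. The collagen gene Col3a1, a mesenchymal marker, rose at least 13.1-fold, from 5.52 ± 1.21 to 9.31 ± 0.21 (n = 3 each).

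Of 20 lens placode genes 9 fell, 3 rose and 8 did not pass, and 10 fell and 4 rose adjusted over the list alone (median -0.85, adjusted p = 7.5e-07). Sox2 went from 10.36 ± 0.21 to 8.32 ± 0.08 and Pax6, a master regulator of eye development, from 11.55 ± 0.16 to 10.58 ± 0.06. The 3 that rose were Mab21l2, by 2.06, and Meis1 and Meis2, by 0.52 and 0.62; Meis1 lies outside the naming rule. The crystallin Cryge fell 24.2-fold, from 10.61 ± 0.08 to 6.01 ± 1.18, though gamma crystallin genes are near-identical and the probe may read several. FGF and ERK response genes fell, 6 of 12 with 6 not passing and 7 down with 1 up adjusted over the list alone (median -1.17, adjusted p = 2.8e-08). Dusp4 and Dusp6, phosphatases of ERK, fell, with log2 changes of -3.37 and -1.45, and Etv5 went from 9.13 ± 0.33 to 4.88 ± 0.63.

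Markers of other tissues rose beside the loss of lens genes. Of 9 endothelial genes 4 rose and 5 did not pass, 7 adjusted over the list alone (median 1.36, adjusted p = 9.0e-07). Pecam1, Emcn and Sox17 were not detected in WT and were at least 2.14-, 2.98- and 2.18-fold higher, and Cldn5 rose by 2.14. Of 12 mesenchyme and neural crest genes 5 rose and 1 fell, 6 not passing, and 6 rose and 1 fell adjusted over the list alone (median 0.98, adjusted p = 0.00010). Alx4 and Twist1, transcription factors of the head mesenchyme, rose by 3.67 and 2.80, as did Col3a1 and, outside the naming rule, Foxc2 by 3.45 and Prrx1 by 1.36. The growth factor receptor gene Pdgfra fell from 10.23 ± 0.03 to 7.74 ± 0.11. Of 8 erythroid genes Hba-x rose by 0.85 and 7 did not pass (adjusted p = 0.10), and 0 of 7 macrophage genes passed (median -0.43, adjusted p = 0.098).

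Pigment epithelium genes rose here too, 6 of 16 with 10 not passing and 7 up with 1 down adjusted over the list alone (median 0.65, adjusted p = 0.00024). Otx2 went from 6.08 ± 0.10 to 8.33 ± 0.19, Otx1 rose by 2.05 and Rab38, a melanosome transport gene, by 1.97. Dct, a melanin enzyme gene, was not detected in WT and was at least 5.70-fold higher. Of 18 neural retina and eye field genes 3 rose and 4 fell, Sox2, Ccnd1 and Pax6 among them (adjusted p = 0.13).

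Further lists were called with the preset correlation and lost with an estimated one. Surface ectoderm genes rose, 4 of 20 with 16 not passing, the 4 being Wnt6, Perp, Trp63 and the AP-2 factor Tfap2b (median 0.31, adjusted p = 0.010, and adjusted p = 0.052 with an estimated correlation). Wnt targets rose, 4 of 12, with Axin2, a feedback inhibitor, up by 2.50, Lef1 by 1.82, Znrf3 by 1.55 and Nkd2 at least 2.66-fold (adjusted p = 0.011 and, with an estimated correlation, adjusted p = 0.052). Of 12 other forebrain genes Emx2 (at least 4.33-fold), Rspo1 and Wnt7b rose (adjusted p = 0.010 and, estimated, adjusted p = 0.052). Of 7 ventral retina genes the forkhead gene Foxd1 rose by 2.38 (list adjusted p = 0.012 and, estimated, adjusted p = 0.052). Wnt7b and Foxd1 were brighter in KO vesicle than in KO ectoderm. Captured vesicle tissue may therefore be part of their rise, which was not tested. Of 12 BMP targets Id2 fell by 0.65, 5 falling and 1 rising adjusted over the list alone (adjusted p = 0.047 and, estimated, adjusted p = 0.098). Tbx3 was not detected in KO and did not pass (adjusted p = 0.077). Of 7 dorsal retina genes Efnb2 fell by 1.35 (list adjusted p = 0.047 and, estimated, adjusted p = 0.11). Of 6 Notch genes Jag1 fell 11.3-fold (list adjusted p = 0.011 and, estimated, adjusted p = 0.12). Of 13 hypoxia and glycolysis genes the glucose transporter Slc2a1, the oxygen sensor Egln3 and the vessel growth factor Vegfa fell, with log2 changes of -0.62, -3.02 and -0.94 (list adjusted p = 0.047 and, estimated, adjusted p = 0.098).

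The other lists were not called in surface ectoderm. Of 17 BMP ligands, receptors and transducers Gdf6 fell by 2.45 and Bmp7 rose by 1.56 (adjusted p = 0.67). Of 17 extracellular matrix genes Has2, a hyaluronan synthase, fell 16.4-fold, Vcan, Sparc and, outside the naming rule, Lamb1 also fell, and Col9a1 rose (adjusted p = 0.43). Of 7 neurogenic genes Isl1 fell by 1.56 and Neurog2 was at least 1.72-fold lower (adjusted p = 0.054). Of 9 retinoic acid genes the binding protein Crabp1 rose by 1.29 (adjusted p = 0.21). Ccnd1 alone fell among 23 cell cycle genes (adjusted p = 0.87), Perp alone rose among 12 CDK inhibitors and p53 targets (adjusted p = 0.30) and the ERK-induced gene Egr1 alone fell among 8 immediate early genes (adjusted p = 0.10). Median and mean differed in sign for the matrix list (0.29 and -0.21, tested downward), BMP ligands (0.13 and -0.10), CDK inhibitors (-0.17 and 0.03) and cell cycle (0.06 and -0.02). The Hedgehog genes Hhip, Ptch1 and Gli1 stood at 0.56, -0.24 and 0.03 and were not tested as a list.

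Among the largest single changes in surface ectoderm, the collagen Col13a1 fell at least 45.9-fold and the neurotrophin receptor Ntrk2 at least 30.1-fold. Prokr1 and the protease inhibitor Spink1 were at least 19.4- and 19.6-fold lower, and Spon2 and Csn3 fell 22.0- and 18.8-fold. Slc38a8, an amino acid transporter, rose 26.6-fold and Trim29 at least 21.3-fold. On the linear scale the rise of Slc38a8 was 28.3% of its level in KO optic vesicle. Vesicle tissue captured with the ectoderm therefore cannot be told apart from expression in the ectoderm for this gene. Masp1, a complement protease, Pf4 and Asb4 were not detected in WT and were at least 14.7-, 10.1- and 10.3-fold higher. Prss35 and Lypd2 rose at least 10.4- and 9.07-fold. The dimmer group was detected on 1 of 3 arrays for Ntrk2, Prss35, Lypd2, Etv5, Axin2 and Isl1 and on 2 of 3 for Col13a1, Col3a1, Trim29, Cldn5, Gdf6 and Rspo1.

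In all, 593 of 11924 genes passed in surface ectoderm, 306 higher and 287 lower in KO, with an unadjusted p below 0.05 in 2172. Of the 593, 586 had separated KO and WT values, as 19.2% of all genes had against 10% by chance. Of the 13 lists called, 5 stayed below 0.05 with an estimated correlation: lens, FGF/ERK, endothelial, mesenchyme and pigment epithelium. With slide as a block 579 genes and 14 lists passed, neurogenic genes being added (adjusted p = 0.047), and 13 of 13 list medians kept their sign within both slides. Within slide 1 (2 arrays per genotype) 19 genes passed. Within slide 2 (1 per genotype) 115 passed, but with the spread of the optic vesicle arrays alone, so this count says nothing about replication in surface ectoderm. Of 65 named genes that passed 30 had over 1 kept probe; in 16 another probe passed in the same direction, in 14 none did, and 1 of 5 dimmer Vcan probes had the opposite sign. The bound for Wnt6 is that of its used probe; a dimmer Wnt6 probe was detected on 1 of 3 WT arrays and rose by 1.65. The count was 339 with array weights, 308 in a fit of these 6 arrays alone and 370 without WT replicate 1, and 8 lists were called without KO replicate 1. Replicates varied more in ectoderm (median SD of a gene 0.36 in KO and 0.32 in WT) than in optic vesicle (0.28 and 0.26), while the main fit shares 1 spread. Optic vesicle gave 412 genes with array weights and 318 in a fit of its own arrays. The excess of 593 genes over the 215 in optic vesicle is therefore not firm. The balance of directions is not firm: without KO replicate 2, 216 were higher and 233 lower, and without KO optic vesicle replicate 2, 261 and 262.

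**Figure D3:**
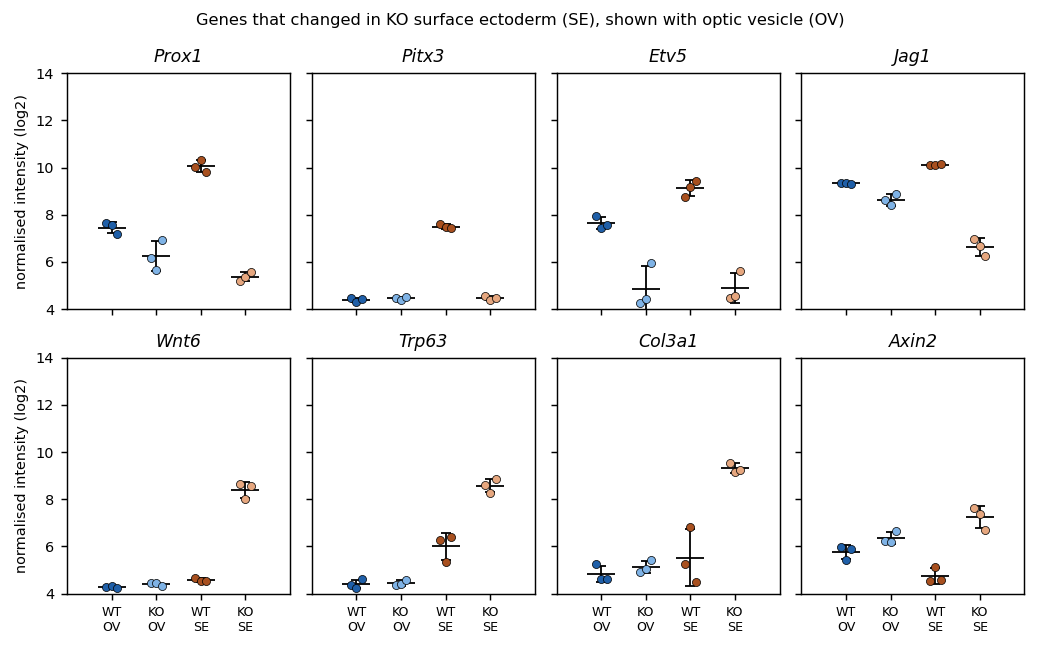
Normalised log2 intensity of 8 genes on each array in all 4 groups, with the mean and SD of each group of 3. In KO surface ectoderm Prox1, Pitx3, Etv5 and Jag1 were lower and Wnt6, Trp63, Col3a1 and Axin2 were higher than in WT.

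**Figure D4:**
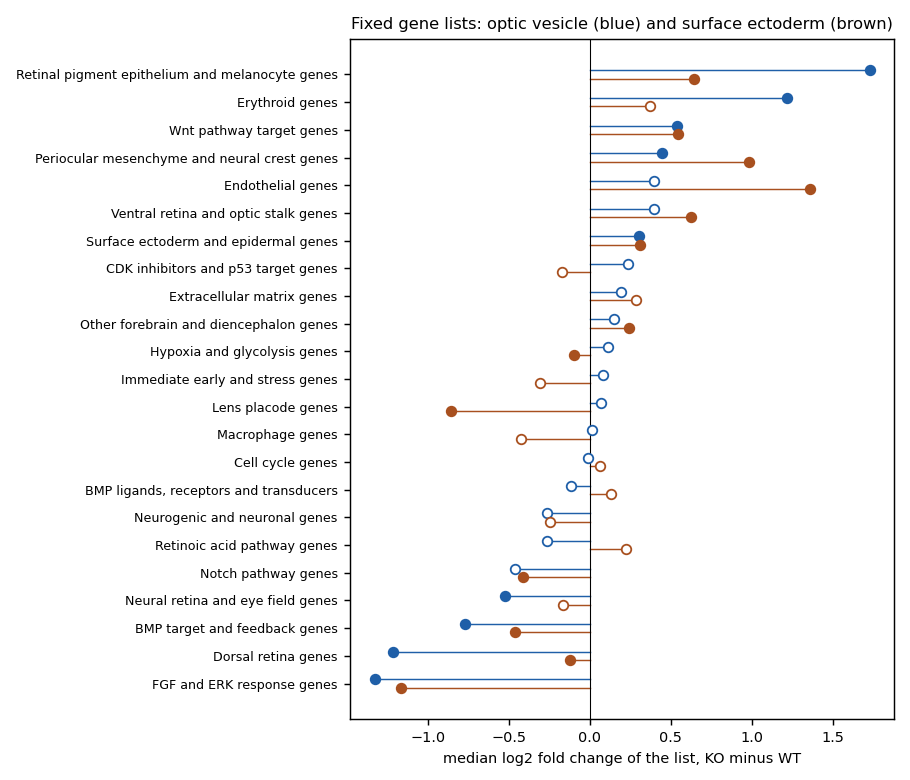
Median log2 fold change (KO minus WT) of the 23 tested gene lists in optic vesicle (blue) and surface ectoderm (brown). Filled points had a camera adjusted p below 0.05 with the preset correlation, and the FGF/ERK list had medians of -1.32 and -1.17.

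A further question was which genes changed in both tissues and which did not. Of the genes that rose, 34 rose in both tissues against 3.18 expected by chance (Fisher's exact test, p = 5.8e-26), Otx2, Pmel, Bmp7, Wnt7b, Alx4 and Pf4 among them. Of those that fell, 32 fell in both against 2.19 expected (Fisher's exact test, p = 3.0e-29), including Sox2, Etv5, Spry2, Dusp4, Gdf6, Efnb2, Id2 and Sowaha. Adjusted over the 4 overlaps these were 1.2e-25 and 1.2e-28. Fisher's test takes genes as independent, which they are not, so these p-values overstate the evidence. For Otx2, Pmel, Dct, Trpm1 and Slc38a8 a shared rise cannot be told apart from vesicle tissue captured with the ectoderm. Wnt7b was likewise brighter in KO vesicle (12.15, 11.99 and 11.78) than in KO ectoderm (10.10, 10.06 and 9.39), and captured tissue was not tested for it. Ctsc, outside the naming rule, and Lamb1 rose in optic vesicle and fell in ectoderm, and Cyp1b1 and Ckb did the reverse. Across all 11924 genes, which are not independent replicates, the effects correlated at Pearson r = 0.21 and Spearman rho = 0.14.

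The interaction tested the difference itself. Cyp1b1 fell by 3.76 in optic vesicle and rose by 1.67 in ectoderm, a difference of -5.42 ± 0.38 (SE, limma adjusted p = 0.00017). Aldh1a1 fell by 4.55 in optic vesicle and stood at 0.15 in ectoderm, a difference of -4.70 ± 0.33 (SE, adjusted p = 0.00017). The collagen Col13a1 fell in both, -1.81 and -5.63 (difference 3.82), Slc38a8 rose by 1.92 and 4.73 (difference -2.82), and the creatine kinase gene Ckb changed by -0.52 and 0.94 (difference -1.47), each with adjusted p = 0.0040. For Slc38a8 captured vesicle tissue may be part of the rise in ectoderm. Of 20 lens placode genes 5 had a higher effect in optic vesicle and 0 a lower one (median difference 0.55, adjusted p = 2.4e-05, and adjusted p = 0.093 with an estimated correlation). The erythroid (median 1.00), pigment epithelium (0.63) and hypoxia lists (0.17) also differed upward and the dorsal retina (-0.83), endothelial (-1.14) and BMP target lists (-0.61) downward. Of these 7 lists 0 stayed below 0.05 with an estimated correlation, the adjusted p then being 0.093 for 6 and 0.14 for BMP targets. Median and mean differed in sign for the surface ectoderm, immediate early, Notch and matrix lists, which were not called.

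In all, 89 genes differed between the tissues, 52 upward and 37 downward, with an unadjusted p below 0.05 in 1457. With slide as a block the count was 80, 7 of 7 list medians kept their sign within both slides, and 0 and 7 genes passed within slides 1 and 2, where 1 tissue has a single array per genotype and the spread is that of the other. The count was 168 without the embryo block, and leaving out any 1 of the 12 arrays gave 7 to 55 genes. Without WT optic vesicle replicate 2 it was 3 upward and 4 downward.

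**Figure D5:**
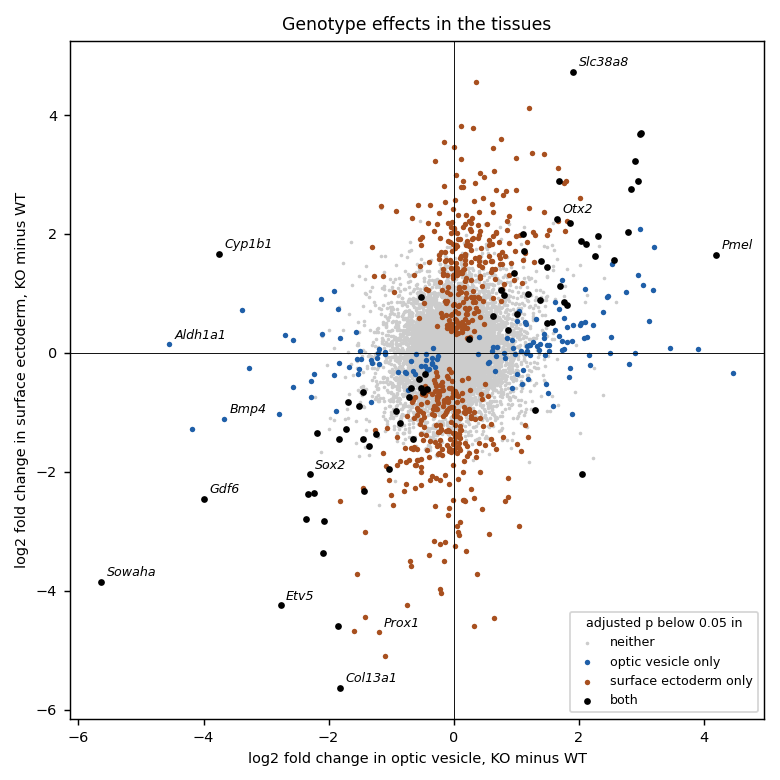
Log2 fold change (KO minus WT) of each of the 11924 genes in optic vesicle (horizontal) and surface ectoderm (vertical), coloured by where the adjusted p was below 0.05. Sox2, Etv5, Gdf6 and Sowaha fell in both tissues, and Cyp1b1 fell in one and rose in the other.

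Comparing the tissues within each genotype asked how far the samples were separate tissues. In WT, optic vesicle exceeded surface ectoderm for the non-coding RNA Miat (5.79 on the log2 scale), the cadherin Cdh11 (5.04), the neural transcription factor Zic1 (4.78), Ildr2 (4.76) and Dipk1c (at least 21.0-fold). Surface ectoderm exceeded it for Spon2 (-6.03), the AP-2 factor Tfap2c (-5.43), Pdgfra (-5.36), the matrix gene Tnc (-5.23) and the tight junction gene Cldn6 (at least 31.5-fold). Retinal Fgf15, Nr2e1 and Mab21l2 were higher in WT vesicle by 4.67, 3.94 and 3.22, pigment gene Otx2 by 2.75 and Trpm1 at least 8.34-fold. In ectoderm Cdh1 (-4.43), Krt18 (-3.05), the lens factor Maf (-3.99), Gja1 (-0.78), Pitx3 (at least 6.69-fold) and the mesenchymal Foxc1 (at least 13.4-fold) were higher, while Alx4 at -1.53 did not pass. The dimmer tissue was detected on 1 of 3 arrays for Miat and Tnc and on 2 of 3 for Cdh11, Nr2e1, Spon2, Pdgfra and Maf.

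In KO, vesicle exceeded ectoderm for Reln (4.64), Lrtm1 (at least 19.4-fold), Pmel (4.33), Dipk1c (4.07) and Zic1 (4.01), and ectoderm exceeded vesicle for Tfap2b (-5.12), Wnt2 (-5.03), the keratin Krt7 (-4.97), Cldn6 (-4.96) and Trim29 (-4.93). Nr2e1, the Wnt receptor Fzd5, Nectin3 and Mab21l2 were higher in KO vesicle by 3.64, 2.69, 1.53 and 2.02, and Meis2 was lower (-0.90). The pigment genes Tyrp1 (at least 6.38-fold) and Trpm1 (3.62) were higher in KO vesicle, as was Postn (at least 12.4-fold), and Dlx3 (-3.91), Foxc1 (-3.76) and Twist1 (-3.12) were higher in KO ectoderm. The dimmer tissue was detected on 1 of 3 arrays for Reln, Dipk1c and Trim29 and on 2 of 3 for Wnt2, Cldn6, Foxc1 and Twist1.

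Surface ectoderm genes were lower in vesicle in WT (14 of 20 lower, median -3.55, adjusted p = 5.5e-24) and in KO (16 of 20, median -3.68, adjusted p = 1.3e-27). Erythroid genes were lower in vesicle in both, 6 of 8 in WT (median -2.23, adjusted p = 6.7e-12) and 5 of 8 in KO (median -1.28, adjusted p = 4.7e-08). Lens placode genes were lower in vesicle in WT, 10 of 20 with 3 higher (median -0.88, adjusted p = 1.4e-06, and adjusted p = 0.10 with an estimated correlation), and 3 were lower and 3 higher in KO (adjusted p = 0.99). Pigment epithelium genes were higher in vesicle in KO, 8 of 16 with 1 lower (median 1.36, adjusted p = 4.7e-08), and 4 with 1 lower in WT (adjusted p = 0.027, and adjusted p = 0.18 with an estimated correlation). Mesenchyme genes were lower in KO vesicle, 7 of 12 with 1 higher (median -2.11, adjusted p = 7.3e-07), and 2 of 12 in WT (adjusted p = 0.0094, and adjusted p = 0.14 with an estimated correlation). Matrix genes were lower in WT vesicle, 6 of 17 with 1 higher (median -0.64, adjusted p = 1.4e-06). Lists called in WT and lost with an estimated correlation were also neural retina (adjusted p = 0.14 with it), ventral retina (0.14), CDK inhibitors (0.15), Wnt targets (0.15) and immediate early genes (0.18). In KO they were endothelial genes, lower in vesicle with a median of -0.72 (adjusted p = 0.11 with an estimated correlation), neural retina (0.13), dorsal retina (0.13), ventral retina (0.16), and retinoic acid, matrix and hypoxia genes (0.11 each). Median and mean differed in sign for the neurogenic and Notch lists in WT and for BMP ligands, lens and FGF/ERK lists in KO, none of them called.

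In WT 805 genes passed, 363 higher and 442 lower in vesicle, and in KO 696 passed, 290 higher and 406 lower; an unadjusted p was below 0.05 in 2403 and 2276. With median scaling 804 passed in WT, 426 higher and 378 lower, so the balance of directions there depends on the scaling. Of the lists, 11 were called in WT and 11 in KO, and 3 and 4 of them stayed below 0.05 with an estimated correlation. With slide as a block 700 and 628 genes passed, macrophage genes being added in WT (adjusted p = 0.041) and BMP targets in KO (adjusted p = 0.044), while the ventral retina list in KO went from an adjusted p of 0.042 to 0.12, and all 11 and 11 list medians kept their sign within both slides. Within slides 1 and 2, 76 and 415 genes passed in WT and 57 and 371 in KO, each time with 1 tissue on a single array that is assumed to vary like the other. With no detection filter the counts were 519 and 450, and leaving out any 1 array gave 350 to 820 in WT and 352 to 616 in KO.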

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

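The tests of captured tissue and of dilution were chosen after the results were seen, while the interaction and the regrouping of the arrays were planned.

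The interaction test called a difference of the genotype effects between the tissues for 89 genes and 7 gene lists. Leaving out any 1 array gave 7 to 55 genes, and 0 of the 7 lists stayed below 0.05 with an estimated correlation, so the count and the lists are not firm. The difference of the log2 effects, optic vesicle minus surface ectoderm, was -5.42 for Cyp1b1, -4.70 for Aldh1a1, -1.47 for Ckb, -2.82 for Slc38a8 and 3.82 for Col13a1. Probes without a single gene symbol, which the comparisons do not use, also changed. In optic vesicle 37 of 4447 such probes passed, 17 higher and 20 lower (0.832%, against 1.24% of named probes), and in surface ectoderm 93, 40 higher and 53 lower (2.09%, against 3.50%).

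Regrouping the arrays asked whether chance can be excluded for each count. There are 10 splits for each genotype comparison and for the interaction and 4 for each tissue comparison, too few for a share under 0.05; in each case the number of splits with as many genes was 1, the real one. The real and the highest other counts were 215 and 1 in optic vesicle, 593 and 1 in surface ectoderm, 89 and 0 for the interaction, 805 and 0 for the tissues in WT and 696 and 0 in KO. Every other split mixes the compared groups, so a true difference between them enters its spread and lowers its count. The gap between these counts therefore does not measure chance.

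The first pattern weighed is the rise of globin genes in KO optic vesicle. Ectoderm tissue taken with the vesicle would need to make up 21.8% to 27.4% of the KO ectoderm level to supply the 4 globins, but 13 bright ectoderm genes outside the pattern had a median share of 2.25% (quartiles 0.752% and 4.35%, highest 16.5%), all 13 below the lowest share needed, which argues against it. The 13 were chosen as not detected in WT vesicle, where the 4 globins were detected on 3 of 3 arrays. Krt18, bright in KO ectoderm and up by 2.04 in KO vesicle, had signal in WT vesicle and so was not among the 13. Its values were 8.75, 8.19 and 8.42 in KO vesicle and 10.03, 9.97 and 9.90 in KO ectoderm. They were like the means of the globin Hba-a1, 8.49 and 10.05. Krt18 thus goes the other way, and captured ectoderm is not excluded. Blood cells captured with the vesicle would bring every bright erythroid gene at 1 share, risen or not. Among the 5 such genes the highest share was 2.13 times the lowest, Hbb-y at 27.4% against Slc4a1 at 12.9%, but over pairs of single arrays Slc4a1 ran from 0.688% to 23.4%, so captured blood and a genotype effect on vessels or blood cannot be told apart.

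The second pattern is the fall of lens genes and rise of genes of other tissues in KO surface ectoderm. Tissue other than ectoderm, if it diluted the capture, would lower surface ectoderm and lens genes alike. The surface ectoderm list had a median of 0.31 and the lens list -0.85, a difference of 1.16 (permutation p = 0.00086, 20 genes in each list). The permutation treats genes as independent, which they are not. Both lists had already been called in these directions in the same data, so its p-value is not separate support. The difference argues against dilution by such tissue as the whole cause. It cannot decide on captured ectoderm from outside the lens region, which would not lower surface ectoderm genes. Mesenchymal or vessel cells in the capture may still account for the mesenchyme and endothelial rise; this was not tested, nor was a change of those cells in KO embryos.

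The third pattern is the rise of pigment genes in KO surface ectoderm, for which optic vesicle tissue taken with the ectoderm is the technical explanation. Rab38 and Otx1 would need it at 48.3% and 172% of the KO vesicle level. Of 20 other vesicle genes 19 stayed below the lower of these, even with the upper limit of their own WT level added to the share, which argues against it for these 2 genes; Pf4, which also rose in both tissues, had the highest share, 104%. Before this addition the median share of the 20 was 11.7% (quartiles 3.44% and 24.0%). The rule picking the 20 vesicle genes and the bound for this test were set after their shares were seen, because a first rule, asking for bright signal in WT vesicle too, left a single gene. Otx2 would need 18.2%, and 11 of the 20 stayed below it with the addition while the other 9 lay above it. Dct, Pmel and Trpm1 would need only 3.55% to 12.1%, and 6 of the 20 lay below that range. Lrtm1 and Postn, with shares of 0.199% and 0.364%, and Reln, with a negative one, go against a share as high as Otx2 or Dct needs, but the shares of the 20 are too uneven to fix 1 value. So for Otx2, Dct, Pmel and Trpm1 carried-over vesicle and expression in the ectoderm cannot be told apart. The same holds for Slc38a8 and Mab21l2, which are among the 20 and had shares of 28.3% and 21.4%. Wnt7b and Foxd1, which also rose in KO ectoderm and were brighter in KO vesicle, are not among the 20 and were not weighed. A change of identity in the KO ectoderm stays open as a biological explanation and was not tested.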

How the results depend on the processing

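The 2 readings of Cdo were added after the results had been seen, and the other alternatives were planned. Apart from leaving out arrays, within 1.5 times of the original count stayed 11 of 13 alternatives in optic vesicle (161 to 412 genes around 215), 10 of 13 in surface ectoderm (308 to 943 around 593), 8 of 12 for the interaction (38 to 168 around 89), 11 of 12 for the tissues in WT (519 to 1165) and 10 of 12 in KO (450 to 1083). With no detection filter the interaction gave 38 genes and the tissue comparisons 519 in WT and 450 in KO. Array weights gave 412 genes in optic vesicle and 339 in surface ectoderm. At an adjusted p below 0.1 the counts were 332 and 943, the interaction 168 and the tissues in KO 1083, since the threshold is looser. The interaction gave 162 genes with embryo as a random block and 168 with no block. In a fit of its own 6 arrays surface ectoderm gave 308 genes and optic vesicle 318. The larger count in ectoderm thus depends on the spread that the main fit shares between tissues of unequal spread. With an estimated correlation 5 lists were called in surface ectoderm and 9 in optic vesicle. The replicate number as a block gave 175 genes in optic vesicle and 477 in surface ectoderm. Where no reason is named, the cause was not tested.

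Leaving out 1 array at a time gave 115 to 226 genes in optic vesicle, 370 to 540 in surface ectoderm, 7 to 55 for the interaction, 350 to 820 for the tissues in WT and 352 to 616 in KO. For the lists only the 6 arrays of the same tissue were left out in turn. This gave 9 to 11 lists in optic vesicle and 8 to 12 in surface ectoderm. A group left with 2 arrays is assumed to vary like the others. The optic vesicle change of Bmp4 ran from -3.92 to -3.52 (adjusted p from 6.2e-05 to 0.0014), and in surface ectoderm from -1.46 to -0.92 (adjusted p from 0.053 to 0.31). Read as Cdo1, the Cdo entry made the ventral list pass in optic vesicle (camera adjusted p = 0.031, 10 lists called), but not with an estimated correlation (adjusted p = 0.078). Read as Cdon it did not pass (adjusted p = 0.30), with 0.056 when the entry was left out. In surface ectoderm the list passed with either reading at the preset correlation. With an estimated one it passed with neither (camera adjusted p = 0.051 as Cdo1 and 0.088 as Cdon).

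Named genes were followed through no background correction, median scaling, the authors' processed values and slide, embryo and replicate blocks, and no value of a named gene changed sign in the first 3. The blocks are balanced between the genotypes, so they change the p-values and cannot change the log2 changes. Of 282 values of the 47 named optic vesicle genes that passed, 11 no longer passed, in Stra6, Gja1, Meis2, Sfrp1, Tpi1 and Vcan, and of 390 values of the 65 in surface ectoderm 9 did not, in Nkd2, Crabp1, Slc2a1, Znrf3, Bmp7 and Sox17. Of 318 and 222 values of named genes that had not passed, 1 and 3 did. The balance of directions was less firm. In WT 363 genes were higher and 442 lower in vesicle, but with median scaling 426 and 378, the median of all genes then standing at 0.10 in place of 0.05, so small tissue differences depend on the scaling. In surface ectoderm 306 were higher and 287 lower, but 216 and 233 without KO_SE replicate 2, and 261 and 262 without KO_OV replicate 2; the interaction had 52 upward and 37 downward, but 3 and 4 without WT_OV replicate 2. Signal over background limits the dim genes: folds against a group with an array at background are bounds, log2 changes against such a group lean on the background level, and without background correction the Bmp4 change in optic vesicle shrank to -1.99.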

Other observations

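The gene groups and genes below, and the tests on the mix of sexes, were chosen after the results were seen. The lists were built around genes already seen to change, so their p-values describe the pattern and are not independent evidence for it.

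Crystallin genes fell together in KO surface ectoderm. Of 16 listed 10 were measured, and 7 fell and 0 rose (median log2 change -2.68, camera adjusted p = 9.8e-15, and adjusted p = 0.00021 with an estimated correlation). Crybb3 was at least 12.1-fold lower and Crygc at least 7.97-fold lower, Crygd went from 8.49 ± 0.16 to 4.77 ± 0.58 (detected on 1 of 3 KO arrays), and Cryab, a small heat shock protein of the lens, fell by 1.44 (n = 3 arrays per group). Gamma crystallin genes are near-identical, so their separate values are uncertain. In optic vesicle 0 of the 10 passed (adjusted p = 0.26). Sterol synthesis genes fell in KO surface ectoderm, 5 of 15 measured with 10 not passing (median -0.71, adjusted p = 5.6e-08, and adjusted p = 0.00096 with an estimated correlation). Insig1, a sensor of sterol levels, fell by 1.62, Msmo1 by 1.07, Hsd17b7 by 1.03, Fdps by 0.78 and Idi1 by 0.69. In optic vesicle 0 of the 15 passed (median -0.20, adjusted p = 0.039, and adjusted p = 0.062 with an estimated correlation). Platelet and megakaryocyte genes rose in KO surface ectoderm, 5 of 10 measured (median 0.93, adjusted p = 0.0017, and adjusted p = 0.016 with an estimated correlation): Pf4 (at least 10.1-fold), Ppbp (at least 4.97-fold), Gp5 (at least 5.65-fold), Clec1b (at least 1.54-fold) and Plek (by 2.27). In optic vesicle Pf4 alone rose (median 0.41, adjusted p = 0.017, and adjusted p = 0.044 with an estimated correlation).

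The following genes were picked by hand from those that passed and were not tested as groups. In KO optic vesicle some changed that act in axon guidance and adhesion. The semaphorins Sema3a and Sema3e fell, with log2 changes of -1.91 and -1.84, the ephrin receptor Epha5 fell by 2.28 and its ligand gene Efna5 rose by 0.94. The teneurins Tenm2, Tenm3 and Tenm4, cell adhesion proteins, rose by 1.68, 1.16 and 1.11. Fgf9, a growth factor of the distal vesicle, was at least 3.68-fold lower and the photoreceptor factor Crx, detected on 1 of 3 KO arrays, fell by 1.84. In KO surface ectoderm the homeobox genes Irx3 and Irx5 rose by 2.55 and 2.72, Irx2 at least 2.05-fold and Osr2 at least 5.54-fold. Pdgfa, a ligand of the receptor Pdgfra, rose in both tissues, by 2.26 in optic vesicle and 1.63 in surface ectoderm, and so did Fgfr2 (1.58 and 0.51) and Igf2 (0.87 and 0.39).

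The hypothesis that each array holds RNA of a single embryo was tested on sex-linked genes. Xist, expressed from the inactive X of females, and at least 2 of 3 Y-linked genes were above background together on 12 of 12 arrays, which argues against it and is in line with pooled RNA. The spread of Xist within groups lay at percentile 74 and that of the Y-linked Eif2s3y at percentile 12.2 of the 500 genes nearest in brightness. The groups were uneven: in KO surface ectoderm Xist varied with an SD of 0.60 (percentile 96 in that group) and Eif2s3y with 0.09 (percentile 1.6), against an Xist SD of 0.06 to 0.16 in the other groups. Whether the arrays of a group hold the same mix of sexes is therefore left open, as is whether they are repeats of a pool.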
